A study of Homo sapiens with 11 samples.

How the data were processed

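CTCF CUT&RUN, in which a nuclease tethered to an antibody releases the DNA around a bound protein, was carried out in HCT116 p53-/- cells, a human colorectal cancer line. The 11 libraries fall into 6 groups: WT, ORC2 deletion and rescue cells, each with a CTCF antibody or with IgG as the background. Per the labels' protocols, the ORC2 deletion cells were a CRISPR/Cas9 clone of the WT cells, and the rescue cells were clones into which ORC2 had been put back on a plasmid. Each group had 2 libraries, except rescue IgG with 1.

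The submitters' processing notes name FastQC 0.11.5, Bowtie2 2.2.9, SAMtools 1.12, MACS2 without a version, and the genome build hg38. Peak calling settings, the treatment of duplicate reads and the use of IgG as a control are not given in the sources used here. The deposited summit lists give 1 base per peak and, as the value of each summit, the −log10 of the peak caller's q, with no scaling between lists. The lowest CTCF values lie between 1.304 and 1.308, just above the −log10 of 0.05. Each of the 3 CTCF lists stands for 1 genotype and names no replicate. It was taken as the pool of its replicates, so no spread between replicates can be given. The depth of the libraries is unknown. The authors' deposited up and down lists give only region starts and ends; they carry no fold, p or other value.

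Summits were put on 1-based coordinates and matched by distance, 100 bp in the main setting. Each share has a 95% Wilson interval, which covers counting error only. A q value per summit was used to rank or filter summits within its own list. Sites were made by joining summits of the 3 CTCF lists that lay within 100 bp of each other, which gave 43812 sites. Site classes were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within each family. Sites are not replicates and neighbouring sites are not independent, so each p describes these lists and not the genotypes. Clustering was tested by 100000 permutations of the up label over the sites.

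Genes came from a RefSeq table of the same human assembly, with 58419 genes used and 679 entries on other scaffolds left out. The table gives gene starts and ends without strand, exons or UTRs. The planned promoter test therefore used the distance to either end of a gene, and the planned nearest transcription start was replaced by the gene that holds the site or else the nearest gene end. The planned tests of the CTCF motif and of GC content need a genome sequence, which was not used here. The planned test of up sites against rescue summits was not run, since the up list holds no region with a rescue summit.

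The rule for named genes was fixed before the data were examined. A protein-coding gene within 50 kb named a site. The text names the first 25 genes of up sites by the deletion list's own value, the first 10 of down sites by the WT value, a panel of 15 genes, and up to 4 genes per gene list and direction. Some of these genes are not reported here. The 19 gene lists were fixed at the same time, and a site counted for a list through its gene.

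The alternatives were distances of 50 and 500 bp, −log10 q minimums of 5 and 10, equal list lengths, other gene windows, 1 site per 100 kb and other backgrounds. Further ones, chosen after seeing the data, used sites that could have passed, 10 classes of the summit value as strata (Mantel-Haenszel odds ratio with an exact conditional p), joining within 500 bp, lists without summits near IgG summits or ORC2, and equal list lengths together with 500 bp. Lists with no change between genotypes were simulated from 35000 to 200000 candidate sites of fixed strength plus noise, set so that WT and rescue lists shared as much as observed. The planned overlap of independent gained lists is not given, since every site absent from WT is gained in deletion, in rescue or in both by construction.

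The matching and the tests were first tested on simulated data. Matching returned 60.2% shared summits where 60.2% had been made. With labels drawn on 31112 deletion sites and lists of 300 sites at an odds ratio of 1.5, Fisher's exact test called 48 of 200 changed lists and 1 of 200 unchanged ones. The stratified test called 99 of the changed lists and 2 of the unchanged ones. Apart from zinc finger genes, with 504 sites, the gene lists tested below had 12 to 298 sites. Changes of this size in the small ones could be missed more often. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.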

Results

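CTCF-bound sites were mapped by CUT&RUN in HCT116 p53-/- cells that were WT, lacked ORC2, a subunit of the origin recognition complex that licenses DNA replication, or had ORC2 put back. CTCF is a zinc finger protein that bounds chromatin loops. The CTCF lists held 19044 summits in WT, 31112 in ORC2 deletion and 20810 in rescue cells, all on chromosomes 1 to 22 and X. The deletion list was 1.63 times and the rescue list 1.09 times as long as the WT list. With −log10 q of at least 10 these ratios were 2.76 and 1.26. With 1 list per genotype and unknown depth, no difference below has a replicate check.

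The IgG lists were short, with 17 summits in WT, 34 in ORC2 deletion and 33 in rescue cells. Of the rescue IgG summits, 6 lay on the mitochondrial genome and 8 on unplaced scaffolds, which left 19 on chromosomes 1 to 22 and X. The other lists had none there, and the rescue IgG list is of 1 library where the others are given per group. Within 500 bp of a CTCF summit of the same genotype lay 14 of the WT, 26 of the deletion and 18 of the rescue IgG summits. Deletion IgG summits lay near 16 of the 17 WT IgG summits.

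The targeted gene, ORC2, spans 200908977 to 200963660 on chromosome 2 (hg38). IgG summits lay inside it in ORC2 deletion, at 200956365 (−log10 q 60.7) and 200958215 (16.3), and in rescue, at 200956416 (11.1) and 200958139 (9.57). The WT IgG list had none there. CTCF summits stood at 200956378 and 200957984 in the deletion list and at 200957000 and 200957858 in the rescue list, where the WT list had none. A further pair, at 200944924 in deletion and 200944929 in rescue, was absent from WT and lay 11441 and 11436 bp from the nearest IgG summit. All 3 CTCF lists had a summit near the gene's upper end, at 200963505 in WT, 200963310 in deletion and 200963522 in rescue. The lists give peaks only, so they do not show whether ORC2 sequence was lost.

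**Figure D1:**
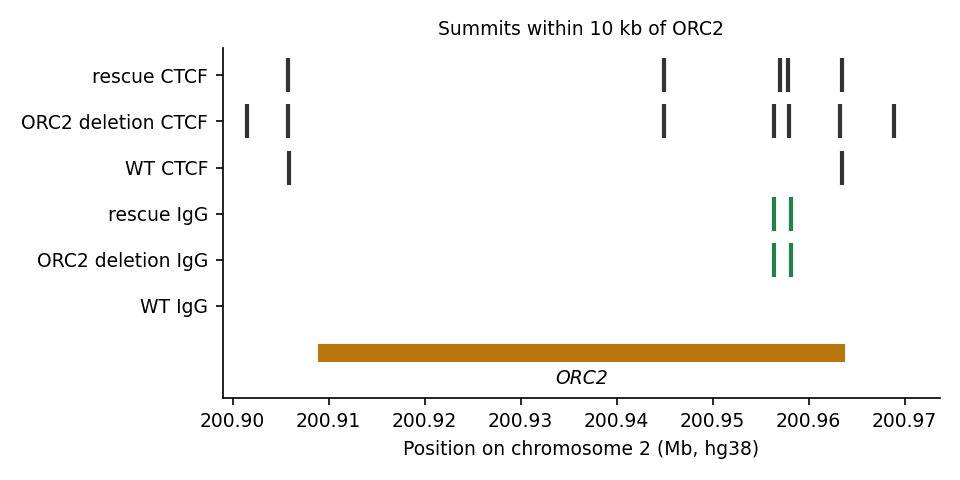
Summits within 10 kb of ORC2 on chromosome 2 (x axis in Mb, hg38), with each list on its own row, 1 tick per summit and the gene as a bar. IgG summits (green) stand inside the gene in ORC2 deletion and rescue and not in WT.

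The first comparison asked whether CTCF sites of WT cells were still called without ORC2. The share depended on the distance allowed: 89.5% of WT summits (95% interval 89.1 to 90.0) had a deletion summit within 500 bp, 60.6% (59.9 to 61.3) within 100 bp and 39.3% (38.6 to 40.0) within 50 bp. In the other direction, 54.8% of deletion summits (54.3 to 55.4) had a WT summit within 500 bp and 37.1% (36.6 to 37.7) within 100 bp. At 500 bp, 14057 deletion summits had no WT summit, whereas 1995 WT summits had no deletion summit. The shares depend on list length too, since a longer list covers more of a shorter one.

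**Figure D2:**
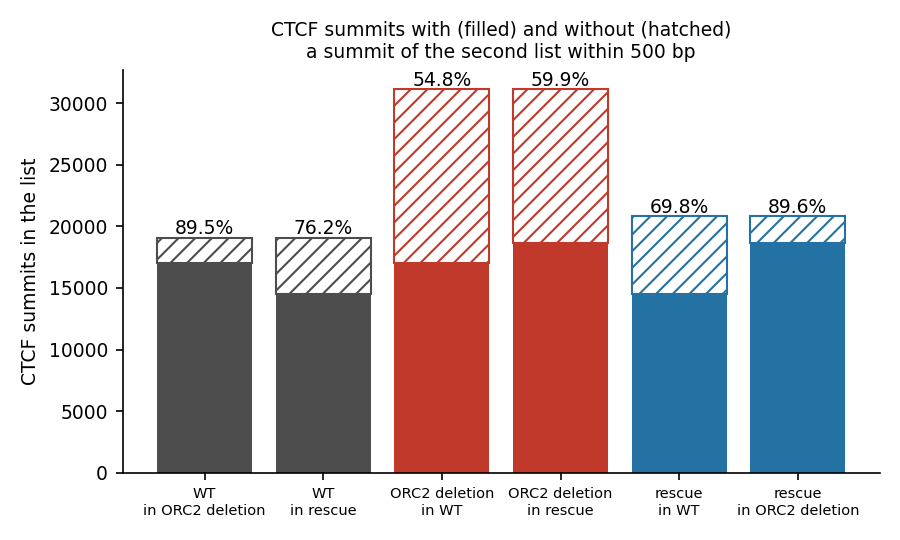
Number of CTCF summits per list (y axis), filled where the second list named under the bar has a summit within 500 bp and hatched where it has none. The share above each bar is 89.5% for WT summits in ORC2 deletion and 54.8% for deletion summits in WT.

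With lists of equal length, the 19044 highest-scoring summits of each, 74.7% of WT summits (74.1 to 75.3) were shared with ORC2 deletion and 73.5% (72.9 to 74.1) with rescue within 500 bp. Deletion and rescue shared 77.2% (76.6 to 77.8). Looked up for the same WT summits, the share found in rescue minus that in deletion was -1.21 percentage points (-1.83 to -0.583). At the 2000 highest-scoring summits it was 0.55 points (-1.47 to 2.57), which does not differ from 0 by its interval.

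**Figure D3:**
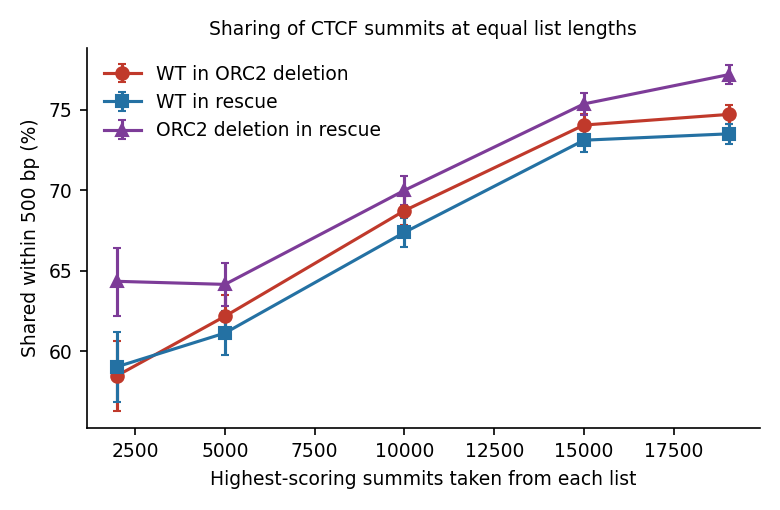
Share of CTCF summits of the first list with a summit of the second within 500 bp (y axis, %), against the number of highest-scoring summits taken from each list (x axis); bars are 95% Wilson intervals. At 19044 summits WT shares 74.7% with ORC2 deletion and 73.5% with rescue.

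The next comparison asked whether summits gained without ORC2 were lost again once it was put back. Within 100 bp, 26.5% of the 19564 gained summits (25.9 to 27.1) had a rescue summit, and within 500 bp 32.3% of 14057 did (31.6 to 33.1). Both genotypes were set against the same WT list. Simulated lists without any change gave 30.6% to 45.7% at 500 bp, depending on the number of candidate sites. Of the 1995 WT summits without a deletion summit at 500 bp, 21.6% (19.9 to 23.5) had a rescue summit, below the 30.3% to 43.9% of the simulated lists of full length. With lists of equal length, at 500 bp, 35.9% of 4815 lost summits (34.6 to 37.3) and 50.3% of 4827 gained summits (48.9 to 51.7) had a rescue summit.

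Summits present in deletion and rescue and more than 1 kb from any WT summit numbered 4442. The highest-scoring ones, taken after their values were seen, lay in RHOBTB2 (chromosome 8, 23019548), in CYP2J2, an epoxygenase of arachidonic acid (chromosome 1, 59947689), and in CACNA1C, a calcium channel subunit (chromosome 12, 2360889). KYNU, an enzyme of tryptophan breakdown, and GNA11, a G protein subunit, also held such summits. The 1473 WT summits with none in deletion or rescue within 1 kb were led by CDKAL1 (chromosome 6, 20550504), CELF4 and ADAMTSL1.

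The authors' deposited lists named 9603 regions up and 364 down, 26.4 times as many up as down. Every up region held a deletion summit and no WT or rescue summit, and every down region held a WT and a rescue summit and no deletion summit. Reversal in rescue is thus part of how these lists are composed and is not a separate result. Of the 9512 deletion summits with no WT or rescue summit within 500 bp, 9477 were in the up list.

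The up sites came mostly from the weak end of the deletion list. Their median −log10 q was 4.34, against 10.8 for the other deletion summits, and 88.5% (87.8 to 89.1) lay below the median score of that list. With the deletion list split by score into 10 classes of equal size, the up list took 79.7% (78.2 to 81.1) of the lowest class and 0.386% (0.221 to 0.673) of the highest. Down sites were weak in WT too, with 78.1% (73.6 to 82.0) below the median score of the WT list.

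**Figure D4:**
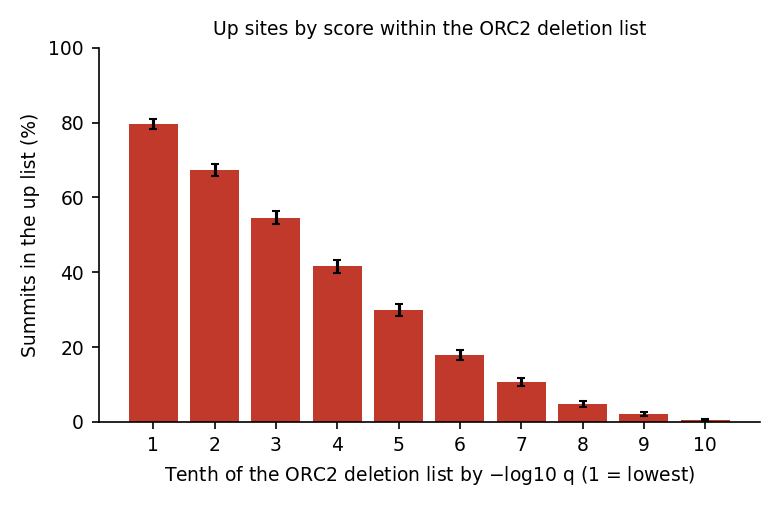
Share of ORC2 deletion summits that are in the authors' up list (y axis, %) in 10 classes of equal size by the list's own −log10 q (x axis, 1 is lowest); bars are 95% Wilson intervals. The share falls from 79.7% in the lowest class to 0.386% in the highest.

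Of the up sites, 7961 had a protein-coding gene within 50 kb, 5693 genes in all, and 4900 lay inside one. The highest-scoring was 112 bp outside EEF1A1, a translation elongation factor (chromosome 6, 73521144; −log10 q 34.1), at rank 860 of the deletion list. Next came sites inside CNIH3, an auxiliary subunit of AMPA receptors (31.9), and KLF11, a zinc finger transcription factor (26.6). Sites inside DRC3, a ciliary protein, MGST2, a microsomal glutathione transferase, and EBF3, a developmental transcription factor, had values of 26.5, 25.1 and 24.6. Among the other genes of the 25 highest-scoring were SOCS2, a suppressor of cytokine signalling (359 bp outside), NR3C1, the glucocorticoid receptor (13307 bp outside), PTPRE, a tyrosine phosphatase, PLCL1 and STIM1, the calcium sensor of the endoplasmic reticulum. They also included ZNF555 (64 bp outside), ZNF808 (266 bp outside) and ZNF608 (inside). The remaining genes were JSRP1, CNTN2, FAM229A, DGCR6L, COL15A1, ARL11, METTL15, NPHP4, BFSP1 and the uncharacterised LOC101927375 and LOC124906010. The 10 highest-scoring of the 25 had no rescue summit within 1 kb of the site, like 9396 of all 9603 up sites. No up site had a rescue summit within 100 bp. The up list holds no region with a rescue summit, so neither is evidence of reversal at these genes.

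The 303 WT summits of down regions with a gene within 50 kb belonged to 299 genes. The highest-scoring was 5855 bp from PHACTR3 (chromosome 20, 59571654; −log10 q 28.0). RPP40, a subunit of RNase P (19.2), F13A1, a coagulation factor subunit (16.1), TRIM38 and SLC22A23 (10.0) followed on chromosome 6, all within its first 30 Mb. CLIC6, SLC39A9, a zinc transporter, TMA16, ABCB1, a drug efflux pump, and USP4, a ubiquitin protease, completed the list.

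Up sites lay within 1 kb of a gene end slightly more often than other sites, 19.7% against 18.5% (odds ratio 1.08, Fisher's exact test, p = 0.00741). Against deletion sites of like score the difference was lost, with an odds ratio of 1.01 (exact test over score classes, p = 0.846). By Fisher's exact test it did not pass at 2 kb (p = 0.146) or with 1 site per 100 kb (p = 0.302). Without regard to score it passed within 500 bp (odds ratio 1.11, Fisher's exact test, p = 0.00296). It also passed for ends of protein-coding genes only (odds ratio 1.17, Fisher's exact test, p = 4.48e-06). Down sites lay there more often, 25.8% against 18.7% (odds ratio 1.51, Fisher's exact test, p = 0.00093). With score taken into account the down odds ratio was 1.44 (exact test over score classes, p = 0.00323), and with 1 site per 100 kb it was 1.10 (Fisher's exact test, p = 0.654). The down odds ratio was 1.86 within 500 bp (Fisher's exact test, p = 3.72e-06). For ends of protein-coding genes only it was 1.77 (Fisher's exact test, p = 3.52e-05).

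None of the 19 gene lists passed Benjamini-Hochberg adjustment over 38 Fisher's exact tests, and 3 tests had an unadjusted p under 0.05. Among zinc finger (ZNF) genes, 132 of 504 sites were up, 26.2% against 21.3% of other sites (odds ratio 1.31, Fisher's exact test, p = 0.00859, adjusted p = 0.327). They were the one list to pass when sites were compared within classes of deletion score, an exact test added after seeing the data (odds ratio 1.58, adjusted p = 0.0341). Over the other alternatives of the exact test their adjusted p was 0.087 against deletion sites, 0.164 within 10 kb, 0.525 with sites joined within 500 bp and 1 with genes as units (odds ratio 1.15). Up sites of this list belonged to 107 genes, led by ZNF555, ZNF808, ZNF608 and ZNF490, and 7 of its sites were down, among them ZNF146 and ZNF777. Ribosomal protein genes had 13 of 102 sites up, 12.7% (Fisher's exact test, p = 0.0387, adjusted p = 0.385), among them RPL3 and RPS3A, and 3 down, at RPS23, RPL5 and RPL30. Within score classes the odds ratio of their up sites went from 0.537 to 1.00 (exact test, p = 1). Of DNA damage response genes 14 of 40 sites were up (Fisher's exact test, p = 0.0507, adjusted p = 0.385), among them RPA1 and CHEK1. Their odds ratio of 1.99 was 2.92 within score classes (exact test, p = 0.0561), 2.05 against deletion sites and 1.08 with genes as units.

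Replication licensing genes, the group ORC2 belongs to, had 12 of 40 sites up (Fisher's exact test, adjusted p = 0.801), at ORC4, GINS4, CDC7 and MCM3 among others, and 0 down. Cohesin and loop extrusion genes had 9 of 55 up (Fisher's exact test, adjusted p = 0.871), with RAD21, PDS5B, STAG1 and NIPBL first. Polycomb and heterochromatin factors had 10 of 66 up, HOX genes 5 of 38, clustered protocadherins 4 of 12, and imprinted genes 19 of 70. HOXB3, PCDHGA4 and L3MBTL1 led these lists, and HOXC9 and PCDHA9 had a down site each. Developmental transcription factors had 70 of 298 sites up, WNT ligands and pathway genes 25 of 111, p53 pathway genes 12 of 41, cell cycle genes 12 of 70 and histone genes 3 of 21. Intestinal epithelium genes, of the lineage this line comes from, had 10 of 64 sites up. Of genes of other cell types, mesenchymal genes had 10 of 49 up, neuronal genes 21 of 89, haematopoietic genes 4 of 17 and olfactory receptors 28 of 133.

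Of the fixed panel, MYC had 2 summits within 10 kb in each CTCF list, and HOXA9 had 1 in each. ORC2 had 2 in WT, 7 in deletion and 5 in rescue, and 2 of its deletion summits were in the up list. ORC4 had 2 in WT, 4 in deletion and 1 in rescue, with 2 up regions, and APP had 2, 4 and 2, with 2 up regions. ORC5 had 1 in WT, 2 in deletion and 0 in rescue, with 1 up region, and ORC6 had 1, 2 and 1. ORC1 and CTCF had 0 in WT and 1 in both other lists. PCDHA12 and CDKN1A had 1 in WT and deletion and 0 in rescue. CDH1, encoding E-cadherin, had 2 in WT and 1 in both other lists. ORC3 and H19 had none in any list.

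By chromosome, the share of sites that were up passed adjustment on 3 of 23 chromosomes. By Fisher's exact test it was higher on chromosome 14 (25.2%, adjusted p = 0.0317) and lower on 19 (19.1%, adjusted p = 0.0317) and X (17.7%, adjusted p = 0.0234). Against sites with a deletion summit, a background added later, only chromosome 19 passed (Fisher's exact test, adjusted p = 0.0355). There the odds ratio was 0.885 for X (Fisher's exact test, adjusted p = 0.414). For chromosome 14 it was 1.19 (Fisher's exact test, adjusted p = 0.0756). With 1 site per 100 kb, 0 chromosomes passed. Up sites formed 2776 neighbouring pairs against 2104 in permuted labels, a ratio of 1.32 (permutation test, two-sided p = 2e-05, the smallest these permutations can give). Permuted labels could fall on any of the 43812 sites, although only the 31112 with a deletion summit can be up. Joining within 500 bp gave 34769 sites with 9594 up, and these were not permuted. The ratio of 1.32 thus depends on how sites were joined and does not show clustering by itself. Among deletion sites permuted within classes of their score, the ratio was 1.04 (permutation test, p = 0.0024).

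In bins of 10 Mb, the first 30 Mb of chromosome 6 held fewer deletion and rescue summits than the rest of the genome. The segment had 193 WT, 189 deletion and 98 rescue summits. Deletion over WT was 0.979 there and 1.64 elsewhere, and rescue over WT was 0.508 there and 1.10 elsewhere. At equal list lengths the segment held 193 WT, 93 deletion and 85 rescue summits. Of 253 bins tested against WT by Fisher's exact test, 0 passed adjustment in deletion (lowest adjusted p = 0.442) and 3 in rescue. By that exact test the 3 were the bins from 0 to 10 and from 10 to 20 Mb of chromosome 6 (adjusted p = 0.0154 for both), and the bin from 130 to 140 Mb of X (adjusted p = 0.0169), where rescue over WT was 2.29. The segment's limits were taken from these values, so a p for the segment as a whole would be too small.

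**Figure D5:**
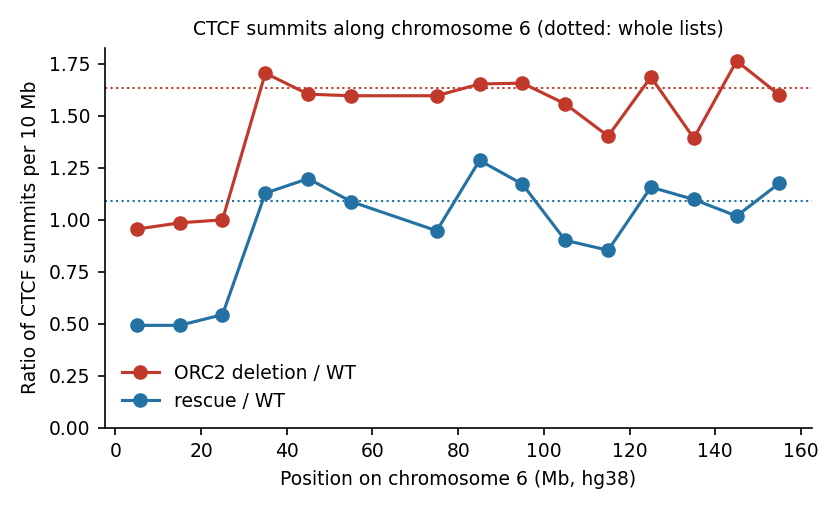
Ratio of CTCF summits to WT (y axis) per 10 Mb of chromosome 6 (x axis, hg38), for bins with at least 30 WT summits; dotted lines are the ratios of the whole lists. In the 3 bins below 30 Mb deletion over WT is 0.955 to 1.00 and rescue over WT 0.493 to 0.544, against 1.63 and 1.09 for whole lists.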

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

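All tests of explanations here were chosen after the results were seen. Signal outside the CTCF measurement was found in the IgG lists. Inside ORC2, the deletion IgG list had 2 summits and the rescue IgG list 2, where WT IgG had none. The rescue IgG list also had 6 mitochondrial summits and 8 on unplaced scaffolds, which the other IgG lists lacked. That list is of 1 library and the others are given per group, so whether all were filtered alike is not known, and these entries are no evidence of a difference between genotypes.

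The CTCF summits inside ORC2 that lie within 1 kb of an IgG summit, at 200956378 and 200957984 in deletion and 200957000 and 200957858 in rescue, are not explained by CTCF binding alone, since 4 IgG summits lie there over the 2 lists. The gene's other CTCF summits were at 200944924 and 200963310 in deletion and at 200944929 and 200963522 in rescue. They lay 5095 bp or more from any IgG summit, and whether they share a source with the IgG summits was not tested. A candidate explanation of the signal near the IgG summits is extra copies of ORC2 sequence left in the deletion clone. Signal without CTCF antibody appears in deletion IgG and not in WT. It appears in rescue IgG too, but rescue cells were given ORC2 on a plasmid, so the rescue list is no separate evidence for this. Open chromatin at the edited gene would give the same lists, and no copy number was measured, so these cannot be told apart.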

How the results depend on the processing

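Of 111 values under alternative settings, 69 kept their side of the threshold or stayed within the interval or 1.5 times the main count. Another 37 moved, and 4 lost and 1 gained significance. Some of the 69 could not move, such as counts on chromosomes 1 to 22 and X for lists confined to them. No result called under both settings changed direction. Chromosome 19, called lower in the main setting, had an odds ratio of 1.01 with 1 site per 100 kb (Fisher's exact test, adjusted p = 0.966). No paired analysis was possible because each genotype has 1 list that names no replicate, and leave-one-out was not possible for the same reason. Motif and GC settings were not run. With −log10 q of at least 5, 11900 WT and 13729 rescue summits remained, and with at least 10, 4433 WT, 12236 deletion and 5564 rescue summits, so that deletion over WT went from 1.63 to 2.76. Rescue IgG had 19 summits on chromosomes 1 to 22 and X. WT summits found in deletion were 39.3% at 50 bp, 89.5% at 500 bp, 68.9% and 75.8% at score minimums of 5 and 10, and 52.7% at equal lengths. Deletion summits found in WT were 24.0%, 54.8%, 36.2%, 27.5% and 52.7% in the same order. Gained sites found in rescue were 20.9%, 32.3%, 27.5%, 22.8% and 40.8%, and lost sites, whose settings were chosen after seeing the data, 23.7%, 21.6%, 31.5%, 26.6% and 28.4%. With equal lengths and 500 bp together, chosen after seeing the data, these shares were 74.7%, 74.7%, 50.3% and 35.9%. Up sites with a rescue summit rose from 0% at 100 bp to 0.802% at 500 bp, and 0.368% with equal lengths too. The distance and the lengths fix much of each share by construction. The odds ratio of up sites at gene ends was 1.04 within 2 kb, 1.05 with 1 site per 100 kb and 1.01 within score classes (added later), none past the threshold, and that of down sites 1.10 with 1 site per 100 kb; fewer sites enter the thinned tests, and otherwise the cause was not tested. Within score classes (added later) 1 gene list passed where 0 had. Chromosomes that passed fell from 3 to 1 against WT sites, 0 with 1 site per 100 kb, and 1 against deletion sites (added later). Chromosome 19 passed against WT and against deletion sites, while 14 and X passed against neither. Unknown depth limits every comparison of list lengths.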

Other observations

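All tests of explanations in this part were chosen after the results were seen. The deletion list was longer than the others, and the up list far longer than the down list. Rank changes that appear without ORC2 and return with it stay open. At equal list lengths the share of WT summits found in rescue minus that in deletion was -1.21 points, but the interval covers counting error only, and at 5000 and 2000 summits it holds 0. A deletion list that reaches weaker sites than the others stays open. Of up sites 88.5% lie below its median score, but summits absent from other lists are weak under any cause, and 78.1% of down sites lie below the median of the shorter WT list. Of the 5 simulations without change, the 1 with 200000 candidate sites held 3 of 7 observed values in its range. These were 89.5% of WT summits found in deletion (89.1 to 89.9 simulated), 14057 gained (13989 to 14139) and 1995 lost summits (1921 to 2071). The 9512 deletion-only summits were in no range and lie between those of 100000 sites (9246 to 9480) and 200000 sites (9617 to 9771). No number between was run, so this miss does not argue against unchanged lists. The 431 summits of WT and rescue alone fell in the range of 1 simulation, with 40000 sites (384 to 450). All 5 gave too many lost summits back in rescue (at least 30.3%, 21.6% observed with full lists). The simulated lists had equal noise, so these misfits cannot decide on a difference in depth. Whether depth or a like rise of CTCF occupancy at all sites made the list longer cannot be told apart: IgG summits were also more numerous in deletion, 34 against 17 in WT, and depth is unknown.

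In the first 30 Mb of chromosome 6, odds ratios against WT at equal list lengths were 0.479 for deletion and 0.438 for rescue. With full lists they were 0.597 and 0.462. The deletion value at equal lengths argues against list length alone. The rescue values argue against an effect of ORC2 loss that rescue reverses. A difference in copy number of one chromosome segment between the clones and WT and an effect of ORC2 loss that rescue did not reverse cannot be told apart, since no copy number was measured. The segment was chosen from these values, 1 bin outside it, from 50 to 60 Mb of X, equals its highest deletion over WT (1.00), and its deletion bins did not pass adjustment one by one. The segment held 8 of the 364 down regions and 48 of the 9603 up regions. Within it, 32.1% of WT summits had no deletion summit within 500 bp, against 10.3% elsewhere, and 59.1% had no rescue summit, against 23.4% elsewhere.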
